A study of Mus musculus with 3 samples.

How the data were processed

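HITS-CLIP libraries of Ptbp2 were made from the testes of 3 CD1 mice. Per the labels' protocols, the first 5 bases of each read came from the 5' linker, which holds random bases, and 79 bases were sequenced. Per the submitters' processing notes, reads were mapped with Bowtie to mm9. The version, the mapping settings, the treatment of reads that map to several places and the removal of duplicates are not given in the sources used here.

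The authors deposited 1 file with a line per read, giving chromosome, both ends, strand, a score and a display colour. The deposited score was 0 on each of the 1727697 lines and was not used. The longest read was 74 nt, which is the sequenced length less the linker bases. No 2 lines had the same chromosome, ends and strand, also between colours, so identical reads had been collapsed over the whole file before deposit. A read found in more than 1 library would then be listed under 1 colour only, which lowers the number of classes seen at a site and flattens the tallest sites. Reads are listed as single intervals, so reads spliced across an intron are not represented.

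The 3 colours were taken as 3 libraries, because there were as many colours as libraries and near-identical reads shared a colour far above the random rate. No label ties a colour to an animal. Values are therefore pooled or given per colour class, with no SD over animals, and p-values between animals were not computed. The depth was 493620 reads in the red class, 952096 in the green class and 281981 in the blue class. Shares have 95% Wilson intervals, which cover counting error only.

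Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Overlapping reads on 1 strand were merged into runs. A cluster was a run with at least 10 reads at its summit and reads from all 3 classes, outside the mitochondrial chromosome. Expected numbers came from 20 draws in which each read kept its length, class and strand and was moved at random within its 10 kb window. Chromosome densities were reads over the span between the first and the last read of the chromosome. Clusters called in 1 class alone were compared by an overlap of at least 1 nt. Class excess in a cluster was tested with a one-sided binomial test against the class's share of all reads, with Benjamini-Hochberg adjustment over all clusters and classes. That test takes single reads as its units and holds no spread between libraries, so it does not test a difference between animals. Cluster calling was tested on simulated data made from the 49080 reads of chromosome 19 placed at random, with 200 planted clusters. It recovered 89.6% of planted clusters of 12 reads, 97.0% of those of 20 reads and 100% of those of 40 reads, and found 0 clusters before planting.

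The design, the alternatives, the gene lists and the rule for named items were fixed before the data were examined. The rule names genes where they can be assigned in the build of the file and otherwise the 10 clusters with the highest summits by position, which was followed here. The only gene table at hand is for GRCm38, and positions were not converted between builds. The planned shares by annotation class, motif counts, distances to splice sites and gene lists, among them the lists of testis cell markers, were therefore not analysed here. The position of reads is described by chromosome and strand instead. Counting reads with equal ends once per class was planned as an alternative and changes nothing, since no such reads remain. Keeping 1 read per 5' end and class, keeping 1 per 3' end after that, random thinning and the joining of clusters into groups were chosen after seeing the data. Keeping 1 read per 5' end also removes separate molecules that happen to share it, and it leaves copies whose 5' ends differ.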

Results

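The data were Ptbp2 HITS-CLIP reads from the testes of adult CD1 mice, 8 weeks old. Ptbp2 is an RNA-binding protein related to the polypyrimidine tract-binding protein Ptbp1, and it regulates alternative splicing. HITS-CLIP sequences the RNA fragments that crosslink to a chosen protein and are recovered with it, and without an input or control library reads from background RNA cannot be told from those of bound RNA. There was 1 group with 3 libraries, each from a different animal, and no comparison group. The title of the series names an alternative splicing network, and the question these libraries address is where on the transcribed genome Ptbp2 was bound in testis. All positions are mm9 positions from the deposited reads, written as counted from 1. Genes, exons and sequence motifs were not analysed here, because no mm9 annotation or sequence was used, so regions are given by position and strand only.

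The deposited reads numbered 1727697, each drawn in 1 of 3 display colours. The green class held 952096 reads, which was 55.1% of the total (95% Wilson interval 55.0 to 55.2). The red class held 493620 reads and the blue class 281981 reads. No label says which colour belongs to which animal, so the colour classes are treated as 3 unnamed libraries and their values are given singly, without an SD. Reads that shared their 5' end and differed by 2 nt at the 3' end had the same colour in 82.4% of 55878 pairs. Neighbouring overlapping reads whose ends were both at least 5 nt apart had the same colour in 42.1% of 202982 pairs, against 41.2% for reads drawn at random. The median read length was 48 nt in the red class, 45 nt in the green class and 47 nt in the blue class, with a range of 20 to 74 nt in each. Intervals cover counting error only, since copies of 1 molecule are not independent.

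Ptbp2 reads were sparse on the sex chromosomes. The X chromosome carried 144 reads per Mb, against 704 reads per Mb over the 19 autosomes, a 4.90-fold lower density. It was the lowest of the 20 chromosomes other than Y in each colour class. The ratio of X to autosome density was 0.222 in the red class, 0.191 in the green class and 0.219 in the blue class. The lowest autosome, chromosome 13, had 598 reads per Mb, which was 4.16-fold above X, and the highest, chromosome 11, had 910 reads per Mb. Chromosomes 17 and 19 followed at 900 and 842 reads per Mb. The assembled part of the Y chromosome carried 383 reads, or 133 reads per Mb. The X chromosome held 1.36% of all reads (95% Wilson interval 1.34 to 1.38). With 1 library per colour and no control library, no test of this difference between animals was made, and the gap between X and the lowest autosome exceeded the spread of the autosomes, which ran from 598 to 910 reads per Mb.

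**Figure D1:**
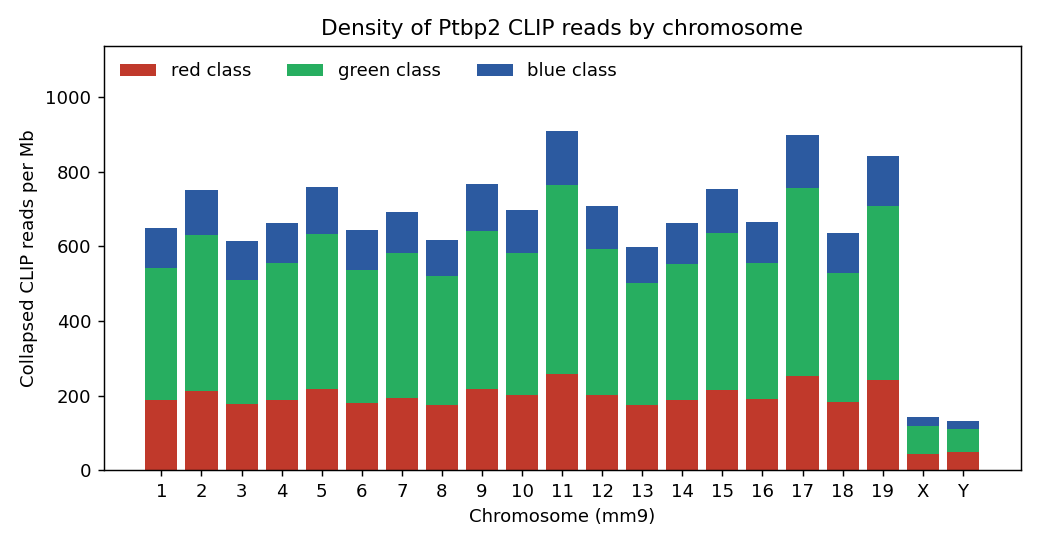
Deposited Ptbp2 CLIP reads per Mb (vertical axis) for each mm9 chromosome (horizontal axis), stacked by colour class, over the span from the first to the last read of the chromosome. The bars of the 19 autosomes end between 598 and 910 reads per Mb, and those of X and Y at 144 and 133 reads per Mb.

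Part of the reads were concentrated in short regions. There were 6509 clusters, defined as runs of overlapping reads on 1 strand with at least 10 reads at the summit and reads of all 3 colour classes, outside the mitochondrial chromosome. They had a median width of 118 nt (interquartile range 87 to 167 nt) and a median summit of 13 reads, and 1239 of them reached a summit of 20 or more. Together they covered 928 kb and held 8.39% of the reads. By contrast, 38.3% of the reads overlapped no other read on their strand. When every read was moved at random within its own 10 kb window and strand, 15.7 ± 3.05 clusters were found (SD over 20 draws, highest 22), so the observed number was 416-fold higher. Random placement within 1 kb windows gave 277 clusters on average, and the observed number was then 23.5-fold higher. Both placements ignore exon and intron boundaries, so background RNA that piles up in exons would also raise these ratios. Part of the height of the clusters came from reads of 1 class with the same 5' end. With 1 read kept per 5' end and class there were 3532 clusters, against 8.75 with random placement, and these overlapped 3523 of the 6509. Keeping 1 read per 3' end after that left 1947 clusters. The number also depended on the deepest class, since 1383 clusters were found without the green class and 3850 without the red class.

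**Figure D2:**
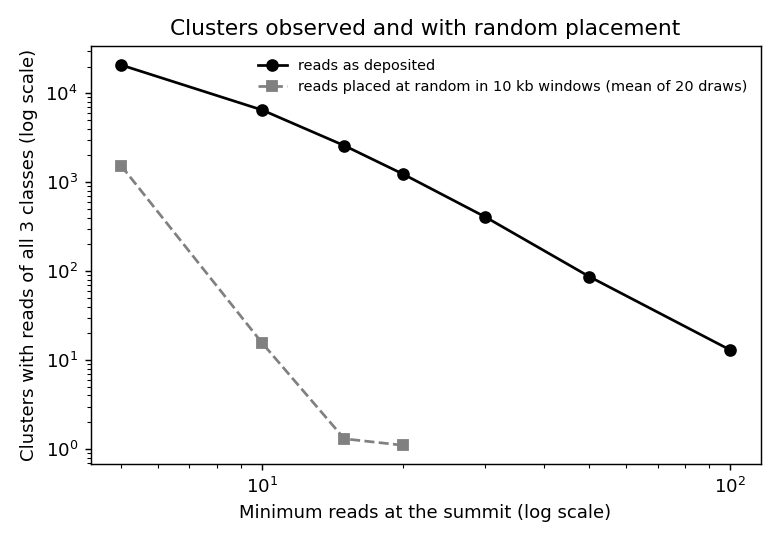
Number of clusters with reads of all 3 colour classes (vertical axis, log scale) by the minimum number of reads at the summit (horizontal axis, log scale), for the reads as deposited and for reads placed at random in 10 kb windows (mean of 20 draws). At a minimum of 10 reads there were 6509 clusters against 15.7 with random placement, and none of the randomly placed sets had a summit of 30 or more.

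The highest summit lay on the minus strand of chromosome 7, from 118219516 to 118219762, where 250 reads overlapped. Chromosome 17 held the second and the eighth of the 10 highest clusters, both on the plus strand. The first of these ran from 39983373 to 39983765 and had 203 reads at its summit, and the other ran from 39984361 to 39985602 with 111 reads at its summit. The third highest, on the plus strand of chromosome 10 from 75313194 to 75313383, had 171 reads at its summit, and 83.7% of its 178 reads were green. Summits of 142 reads were found on the plus strand of chromosome 5, from 129260073 to 129261041, and on the plus strand of chromosome 3, from 145948788 to 145948899. In the chromosome 3 cluster 90.7% of the reads were green, against 63.0% in the chromosome 5 cluster. The other 4 lay on chromosome 9 (minus strand, 78023101 to 78023251, summit of 124 reads), chromosome 14 (minus strand, 101597656 to 101598301, summit of 117 reads), chromosome 11 (minus strand, 33994115 to 33994413, summit of 110 reads) and chromosome 6 (plus strand, 47731621 to 47731765, summit of 108 reads). With 1 read per 5' end and class, all 10 were still clusters, with summits of 48 to 125 reads. With 1 read per 3' end kept after that, they were still clusters, with summits of 21 to 79 reads, and the chromosome 10 summit fell from 171 to 23 reads. Identical reads had been collapsed before deposit, so the heights of the tallest clusters are lower bounds on the reads sequenced there. No genes were assigned, so clusters in ribosomal, transfer or small nuclear RNA genes were not left out and may be among these 10.

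Clusters occurred in groups along single strands. When same-strand clusters up to 10 kb apart were joined, a distance chosen after the data were seen, 531 clusters (8.16%) lay in 34 groups of 10 or more. Reads picked at random in the same number gave a median of 0 and at most 32 such members in 100 draws. Clusters need 10 overlapping reads and single reads do not, so clusters favour densely covered stretches more than these draws do. The draws therefore do not separate grouping of clusters from read density. The largest group held 34 clusters in 27.3 kb on the minus strand of chromosome 10, from 18520505 to 18547809, with 1655 reads there on the minus strand and 13 on the plus strand. All 3 classes contributed, with 456 red, 907 green and 292 blue reads. The next groups held 30 clusters on the minus strand of chromosome 3 from 20329446 to 20377614, 25 on the minus strand of chromosome 13 from 50611215 to 50665349, 24 on the plus strand of chromosome 17 from 34540820 to 34585622, and 23 on the plus strand of chromosome 7 from 89321565 to 89349116. With 1 read per 5' end and class, these 5 regions held 26, 23, 16, 17 and 15 clusters, and with 1 read per 3' end kept after that 18, 15, 14, 14 and 11.

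**Figure D3:**
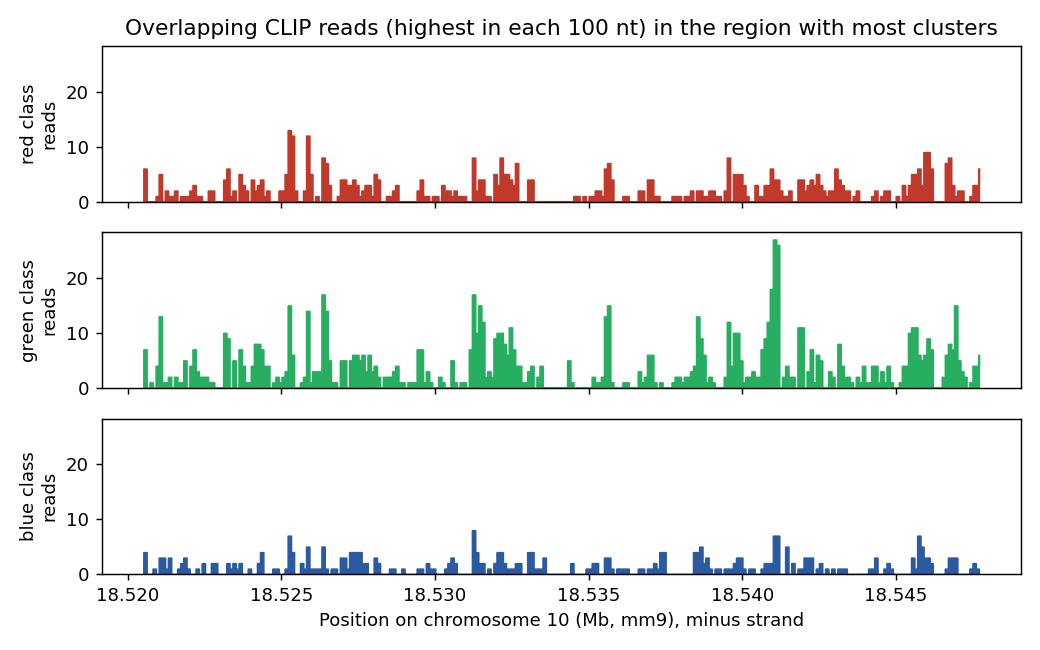
Overlapping CLIP reads (vertical axis, the highest number in each 100 nt) along the minus strand of chromosome 10 (horizontal axis, Mb, mm9) in the region from 18520505 to 18547809, 1 panel per colour class. The 34 clusters of the region are spread over its 27.3 kb, and reads of all 3 classes occur along it.

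The X chromosome held 46 clusters, or 0.281 per Mb, against 2.67 per Mb over the autosomes, where the lowest chromosome had 2.12 and the highest, chromosome 17, had 4.37 per Mb. A single group accounted for 18 of the 46. It spanned 17.4 kb on the minus strand from 132206888 to 132224286, with a highest summit of 27 reads. The remaining 28 clusters made 0.171 per Mb. With 1 read per 5' end and class the X chromosome held 25 clusters, 10 of them in that group, and with 1 read per 3' end kept after that 14 clusters, 5 of them in that group.

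The reads were strongly stranded. In the 45011 windows of 10 kb with at least 10 reads, 95.8% of the reads lay on the window's main strand, and 67.5% of the windows had reads on 1 strand only. Within the bounds of the 6509 clusters, 68 reads lay on the opposite strand, which was 0.0469% of the reads there (95% Wilson interval 0.0370 to 0.0595). None of the 6509 clusters overlapped a cluster of the other strand. Of the clusters, 51.4% lay on the plus strand.

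The colour classes were compared by calling clusters in each alone, again with at least 10 reads at the summit. The red class gave 478 clusters, the green class 2658 and the blue class 177. Of the red clusters, 64.0% overlapped a green cluster (95% Wilson interval 59.6 to 68.2) and 15.1% a blue cluster. Of the blue clusters, 52.5% overlapped a green cluster and 40.1% a red cluster. Of the green clusters, 11.6% overlapped a red cluster and 3.54% a blue cluster, at the lower depth of those classes. A read of the red class was present in a run overlapping 90.3% of the green clusters, and a read of the blue class in 80.1% of them. Across 181243 strand-specific windows of 10 kb with at least 1 read, Pearson's r of log2(reads + 1) was 0.70 between red and green, 0.65 between red and blue and 0.67 between green and blue, and Spearman's rho was 0.54, 0.49 and 0.52. These correlations are across windows, which are not independent replicates.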

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

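All tests below were chosen after the data had been seen. For those that keep 1 read per 5' end, the prediction was written before the value it gave was seen.

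The mitochondrial chromosome, which was left out of the cluster comparison, carried 1216 reads. This was 0.0704% of all reads, and 95.5% of them lay on the plus strand. By the same rule it held 10 clusters, the highest from 1822 to 2765 with 68 reads at the summit and the widest from 366 to 1687. Unplaced sequences of the assembly carried 1654 reads on 7 sequences and 10 of the clusters.

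The X chromosome had 0.204 of the read density of the autosomes, where a single copy in males would give about 0.5. The highest of the 3 classes was at 0.222, so copy number alone does not account for it. Reads confined to fewer parts of X would leave the busiest parts at autosome-like levels, but the 99th percentile of 100 kb windows on X was 0.171 of that on the autosomes, at 97.7 reads against 571 reads, and below the 449 reads of the lowest autosome. With 1 read per 5' end and class the ratio was 0.209. That step kept 85.9% of the reads, too many for the ratio to come near 1 whichever reads were removed. It therefore does not decide whether copies left in the file play a part. Low transcription of X in the cells that contain Ptbp2, fewer genes in every part of X and repeats spread along it to which reads cannot be assigned stay open and were not tested, since the design holds no other tissue or input library and no mm9 sequence or annotation was used.

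Of the 6509 clusters, 48 held more green reads than the green share of all reads (one-sided binomial test, Benjamini-Hochberg adjusted p under 0.05), among them 4 of the 10 highest summits. An excess of red reads was found in 15 and of blue reads in 43. Green made 55.1% of all reads and each cluster had to hold all 3 classes, so clusters of few reads could not reach a green excess. The median reads per cluster in excess were 60 for green, 29 for red and 17 for blue. The 3 counts and the share among the highest summits therefore follow in part from the number of reads. Runs lacking a class, among the 8151 with at least 10 reads at the summit, were not tested. Copies of single molecules with shifted 3' ends were considered as a source (copies of reads left in the file that share their 5 prime end). With 1 read per 5' end and class, 0 clusters kept a green excess. The same step left 1 cluster with a red and 1 with a blue excess, and random thinning to the same number of reads per cluster left 12.7 clusters in green excess on average over 10 draws (range 7 to 16), so loss of reads accounts for much of the drop but not for the last of it. In the 48 clusters the commonest 5' end held a median of 8.79% of the reads and the commonest 3' end 18.6%. The reads thus stacked more on a shared 3' end than on a shared 5' end. Copies with shifted 3' ends would share their 5' end, so this stacking is not the kind that they would give. In the other clusters, with lower summits, the medians were 21.4% and 19.4%. Copies and a true difference between the animals cannot be told apart for the 48 clusters, because keeping 1 read per 5' end takes most reads from the class with most reads at a site, whatever their origin. A read found in more than 1 library is listed under 1 colour only, which may also shift the class counts at the tallest sites. The binomial test counts reads as independent, which copies of 1 molecule are not, so its p-values may be too small.

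Reads sharing a 5' end and differing by 2 nt at the 3' end had the same colour in 82.4% of pairs, which argues against colours unrelated to libraries. With the 3' end shared, the same-colour share was 78.7% at a difference of 1 nt and 51.2% at 5 nt, while with the 5' end shared it was still 71.5% at 5 nt and 71.9% at 20 nt. Copies made during amplification whose 3' ends were read or trimmed differently are a candidate explanation, and no test separates these from binding sites with a preferred 5' end that differs between animals.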

How the results depend on the processing

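The alternatives that keep 1 read per end and the random thinning were chosen after seeing the data; the others were fixed before. The 6509 clusters became 20868 with a summit of at least 5 reads, 1239 with at least 20, 3532 with 1 read per 5' end and class and 1947 with 1 per 3' end after that, while random thinning to as many reads as the first leaves gave 4786, and requiring 2 of 3 classes gave 7976. Leaving out 1 class at a time gave 1383 to 5617 clusters, the lowest without green and the highest without blue. The excess over random placement, 416-fold, was 13.5-fold with a summit of at least 5 reads, 1126-fold with at least 20, 23.5-fold with 1 kb windows, 278-fold with 1 read per 5' and 3' end, and 254-fold to 987-fold with 1 class left out. Random placement gave a mean of 1542 clusters with a summit of at least 5 reads and 1.1 with at least 20. Without the red class, where the excess was 987-fold, it gave 3.9. The largest ratios thus rest on few random clusters. The excess was above 1 under every setting run. Spearman's rho between red and green rose from 0.54 to 0.61 in windows of at least 10 reads, between green and blue from 0.52 to 0.56, and between red and blue from 0.49 to 0.52. Pearson's r fell in the same windows, from 0.70 to 0.64, from 0.67 to 0.60 and from 0.65 to 0.55 for these pairs. The X share of reads, 1.36%, was 1.40% with 1 read per 5' end, 1.41% with 1 per 3' end after that, and 1.31% to 1.47% with 1 class left out. Requiring an overlap of 50% of the shorter cluster moved no shared percentage outside its interval. The cause of these shifts was not tested, beyond the fewer reads or clusters that the settings admit by construction. No paired analysis was possible because the series has 1 group. Depth limits the comparison of classes: in the blue class 177 clusters reached 10 reads. Alternatives for motifs, splice sites, gene lists and annotation classes were not run.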

Other observations

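The number of clusters differed between the classes when each was drawn down to the same number of reads. Identical reads had been collapsed before the draws, so the draws match the reads left in the file and not the sequencing depth. With every class drawn down to 281702 reads outside the mitochondrial chromosome, the blue class had 177 clusters of at least 10 reads, the green class 139.3 (mean of 10 draws, range 124 to 145) and the red class 77.8 (range 67 to 86). With 1 read per 5' end and then drawn down to 243851 reads, the numbers were 46 in the blue class, 25.8 in the green class (range 22 to 30) and 20.7 in the red class (range 16 to 24), whose ranges overlap. With 1 read per 5' end, then 1 per 3' end, and 236012 reads, the blue class had 12 clusters, the red class 5.4 (range 4 to 7) and the green class 1.4 (range 0 to 3). Blue, the shallowest class, was highest in all 3 settings, while green was above red with the reads as deposited and below it in the last. The order in each setting cannot be told apart from the removal of reads at full depth before the draws. No difference in stacking between the libraries is therefore concluded.

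Read lengths of 43 and 59 nt were over-represented in the green class only among the lengths compared. Reads of 43 nt made 5.93% of the green class, against 3.85% at 42 nt and 3.66% at 44 nt, and reads of 59 nt made 2.57%, against 1.82% at 58 nt and 1.59% at 60 nt. In the red class 43 nt reads made 3.42% and in the blue class 3.00%, close to the lengths beside them.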
